A study of Drosophila melanogaster with 10 samples.

How the data were processed

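The data are 10 libraries from OSC cells grown at 26 °C and collected 2 days after siRNA transfection: 6 of poly(A) RNA and 4 of chromatin immunoprecipitated with the Pol II antibody 8WG16 after shearing to 200 bp, per the labels. Each group of the design holds 1 library. No chromatin input library was used here.

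RNA values were deposited by the authors as RPKM (reads scaled by length in kilobases and by library total), per the file headers, for 177 TE entries and for genes at named loci. Pol II values were deposited by the authors as RPM (reads scaled by library total alone), per the file headers, for the same 177 entries. The submitters' processing notes name cutadapt, Bowtie2 2.0.0, TopHat2 2.0.7 and Cufflinks 2.0.2 for the RNA libraries, cutadapt and Bowtie2 2.0.0 for the Pol II libraries, and genome build dm3. The TE sequence set, the gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here, so reads shared between related families or gene copies may be counted in any of them. Gene loci are printed as the files give them; whether their starts count from 0 or from 1 is not stated. A gene table of another assembly, release 6, served only to match names: 13904 of 13984 gene names were found as symbol or synonym.

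Depth was computed from the values themselves. In the Pol II files every value is a whole multiple of the value of 1 read, within 0.01 reads, so totals and reads per family follow directly, and 100% of the values above 0 came out whole. In the RNA files the ratio of a family's values between libraries is a ratio of whole read numbers, and a search for the library totals and family lengths that make every value whole, within 0.002 reads or the rounding of the file, gave whole reads for 151 of 152 entries above 0. The other 25 RNA entries and 29 Pol II entries were at 0 in every library. On simulated libraries this search found 60 of 60 totals and every read number of 98.0% of 1510 families. A comparison of these Pol II reads family by family was also run and then left out, as the files hold too few low values to check the recovery independently. A search of this kind returns a best fit, not a record of the sequencing run. Intervals of a ratio are 95% exact binomial (Clopper-Pearson) intervals on these reads; in the simulation they held the true ratio in 96.4% of 384 cases. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only.

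Changes were computed as log2((knock-down + 1)/(control + 1)) on the deposited values, with a pseudocount of 1 in the unit of the file, so changes of low features are understated; printed folds are plain ratios without a pseudocount. Families and genes with a mean of at least 1 over the libraries of an assay entered counts. A feature high in 1 library can therefore enter through that library alone. Every deposited TE entry is called a family here, also entries in no list whose names are not those of TE families. Examples in the counts are 5S and DMSAT6 in Pol II and DEC1_DS in RNA. Others may be parts of a family, such as COPIA2LT, with a recovered length of 198 bases. As no test was possible, fixed size limits of 2-fold for RNA and 1.5-fold for Pol II stood in its place. These limits, the gene and family lists, the naming rule and the alternatives were fixed before the data were examined, apart from those said to be added later. Of 14145 gene entries, 161 repeated a gene name and were summed with the first. In simulated libraries of the Piwi comparison, 40.3% of 67 genes with a true 2-fold difference, 94.0% of 67 with 4-fold and 95.5% of 66 with 8-fold were past the limit, and 0 of 7490 unchanged genes were. The simulated noise was normal, with a spread taken from the middle of the observed changes, so it held no outlying values. The 0 is therefore no estimate of false calls in the real libraries.

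Named families are, per knock-down, the 6 highest and 3 lowest log2 changes past the limit, plus GYPSY, MDG1, DM297, DM412, BLOOD, ZAM, IDEFIX, DM176, GTWIN, ROO, COPIA, DOC, I and HETA in any case. Named genes are the 6 highest and 6 lowest past 2-fold with a mean of at least 5 RPKM, the 5 targeted genes, and the 2 to 4 members of each list with the largest change. Short RNA genes took most of the lowest places, so the next genes by the same order are named in their stead; this and the families or genes in groups found by sharing were chosen after the values were seen.

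The fixed gene lists were piRNA pathway, heterochromatin factors, germline markers, follicle markers, hemocyte and fat body markers, neuron and muscle markers, antimicrobial peptides and immune genes, siRNA and miRNA machinery, heat and stress genes, apoptosis and DNA damage genes, S and M phase genes, pericentromeric genes, chromosome 4 genes, and ex alone, a gene reported beside a gypsy insertion in OSC; the insertion was not examined here. Genes on heterochromatic or unplaced arms were added after seeing the data. The fixed TE lists were errantivirus-type, other Ty3/gypsy-type, Bel/Pao-type, Copia-type, non-LTR, telomeric, and DNA transposons with helitrons, and 102 of the 177 entries matched a list. A list's median log2 change was placed among 10000 random lists of the same size matched on mean level, in 10 bins for genes and 3 for families, as a description of these libraries and not a p-value; percentiles of different knock-downs share 1 control and are not independent.

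Similarity between knock-downs was given as correlation, covariance and shared features, beside values from simulated unchanged libraries against the same control (1000 simulations for families, 100 for genes, with noise taken from 200 genes of like level) and beside the overlap of independent lists. Alternatives were other pseudocounts (0.1 and 5), other filters (none, and a mean of at least 10), centring on the median gene or family, scaling to the total over families, other size limits and transcript entries counted separately. Added after seeing the data were families of the fixed lists alone, genes without short RNA genes and genes without those that share at least 80% of their locus with another. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.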

Results

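RNA levels and RNA polymerase II (Pol II) occupancy were measured in Drosophila ovarian somatic cells (OSC), a cultured line of somatic cells of the ovary, 2 days after transfection with siRNAs. Poly(A) RNA was sequenced from 6 cultures: a control treated with an siRNA against EGFP, and 5 knock-downs, of Mael, Piwi, HP1a, Armi and CG3893. Pol II chromatin immunoprecipitation covered 4 cultures: the control and the knock-downs of Piwi, Mael and CG3893. Each group held 1 library, so no difference has a replicate check, no p-value is given, and the 95% intervals cover counting error only. The RNA libraries held 33872728 reads in the control, 36729626 in Piwi, 22307339 in Armi, 25393324 in Mael, 31482093 in CG3893 and 18584526 in HP1a. The Pol II libraries held 4114686 reads in the control, 3468976 in Piwi, 3313513 in Mael and 4221772 in CG3893.

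The targeted genes were lower in the libraries of their own knock-downs. The RNA of piwi, which encodes the nuclear PIWI protein of these cells (chromosome 2L, 10982204 to 10987416 in build dm3), stood at 576 RPKM in the control and at 174 RPKM, 30.1% of control, in the Piwi knock-down. The RNA of armi, an RNA helicase gene needed to make piRNAs (3L, 3461322 to 3466314), went from 469 to 168 RPKM, 35.9% of control. That of mael (3L, 22717333 to 22719334) went from 87.2 to 9.01 RPKM, 10.3% of control. CG3893, a zinc finger gene of the nuclear piRNA pathway (3L, 18893688 to 18894593), went from 23.5 to 11.4 RPKM, 48.4% of control. The HP1a gene, which encodes a protein that binds methylated histone H3 in heterochromatin (2L, 8209625 to 8211133), went from 397 to 120 RPKM, 30.2% of control. In libraries of other knock-downs these 5 genes lay between 73.8% of control, for piwi in HP1a, and 119% of control, for armi in Piwi.

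**Figure D1:**
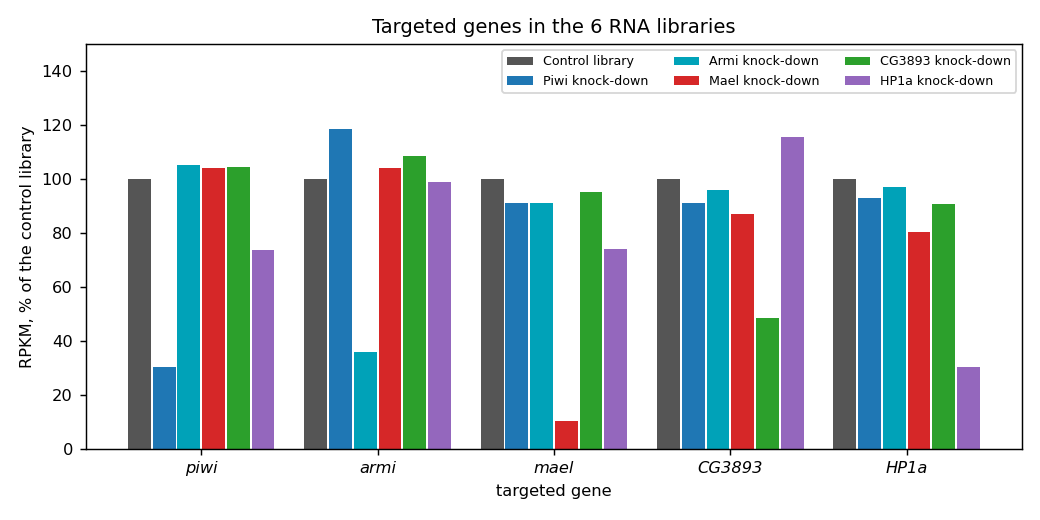
RNA of the 5 targeted genes in each of the 6 RNA libraries, as a percentage of the control library's RPKM (vertical axis), with 1 bar per library. In its own knock-down each gene stands between 10.3% and 48.4% of control.

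The RNA-seq comparison asks which transposable element (TE) families hold more RNA when a piRNA factor or HP1a is depleted. The share of all reads assigned to the TE families was 7.49% in the control (7.48 to 7.50), 10.4% in Piwi, 8.83% in Armi, 11.7% in Mael, 9.37% in CG3893 and 12.8% in HP1a. COPIA and Gypsy1, the most abundant families, held 6.17% of the control reads. COPIA was between 5896 and 6864 RPKM in all 6 libraries, and Gypsy1 went from 4104 RPKM in the control to at most 5545 RPKM, in HP1a. Without these families the share was 1.32% in the control, 3.85% in Piwi, 2.45% in Armi, 5.05% in Mael, 2.86% in CG3893 and 5.68% in HP1a.

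In the Piwi knock-down, RNA of the LTR retrotransposon MDG1 was 853 RPKM against 5.45 in the control, 156-fold higher (148 to 165). GYPSY, an endogenous retrovirus of the ovarian soma, was 32.4-fold higher (31.7 to 33.1), at 1125 against 34.7 RPKM. DM297 was 17.5-fold higher, TABOR 15.5-fold, DM412 14.3-fold and STALKER4 11.5-fold. BLOOD was 8.05-fold higher, and the LINE-type elements DOC and I were 2.66-fold and 2.40-fold higher. IDEFIX, at 17.0 against 17.98 RPKM, and the telomeric element HETA, at 4.77 against 5.01 RPKM, were close to control. Of 119 families with a mean of at least 1 RPKM, 23 were past 2-fold higher and 0 past 2-fold lower on the log2(RPKM + 1) scale, and the median log2 change was 0.24. GYPSY and MDG1 together made up 43.4% of the added TE reads.

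In the Armi knock-down the same kinds of families led, at smaller ratios. MDG1 was 21.2-fold higher than control (20.1 to 22.5), GYPSY 15.0-fold and DM297 7.21-fold. STALKER2 was 6.46-fold higher, BLOOD 5.81-fold and STALKER4 6.47-fold. ROO, at 1.48-fold, and GTWIN, at 1.15-fold, were under the 2-fold limit. In all, 13 of the 119 families were past 2-fold higher and 0 lower, with a median log2 change of 0.19.

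In the Mael knock-down MDG1 reached 1628 RPKM, 299-fold above control (283 to 316). DM297 was 39.6-fold higher, DM412 37.2-fold, TABOR 32.4-fold, GYPSY 29.5-fold and QUASIMODO 27.1-fold. ROO was 4.53-fold and DOC 4.40-fold higher. TOM was the only family past 2-fold lower in any knock-down, at 1.20 against 3.47 RPKM. It held 0 reads in each of the 4 Pol II libraries, and whether its RNA reads come from a related family was not tested. Of the 119 families, 42 were past 2-fold higher, with a median log2 change of 0.49, and 22 of the 23 families higher in Piwi were among them. GYPSY5 was not, with a change of 1.00 just under the limit on the log2(RPKM + 1) scale, which understates plain ratios. On the same scale a further 18 families, among them the LINE-type elements BS2, FW and IVK, were past 2-fold in Mael but in none of Piwi, Armi and CG3893. For some of these the pseudocount decided this: plain ratios in Piwi, Armi and CG3893 were 3.07, 2.62 and 2.63 for HELENA and 2.80, 2.49 and 2.70 for Transib5, and GYPSY12A was at 2.11 in Piwi, BS at 2.19 and GYPSY11 at 2.01 in CG3893.

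In the CG3893 knock-down MDG1 was 136-fold higher than control (129 to 144), at 742 RPKM. DM297 was 14.1-fold higher, GYPSY 13.4-fold, QUASIMODO 12.96-fold, DM412 9.29-fold and TABOR 8.00-fold. I stood at 1.31-fold and DM176 at 1.24-fold. In all, 16 families were past 2-fold higher and 0 lower, with a median log2 change of 0.24. CG3893 RNA remained at 48.4% of control in this library.

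In the HP1a knock-down QUASIMODO was 148-fold higher than control (142 to 155) and reached 1394 RPKM. FROGGER, a Copia-type element, stood at 150.5 RPKM against 0.67 in the control, 223-fold higher (170 to 300). MDG1 was 84.2-fold higher, DM297 54.1-fold, STALKER4 35.7-fold and GYPSY 28.1-fold. ZAM, which was 2.16-fold to 3.16-fold above control in the other knock-downs, was 24.1-fold higher here, at 49.2 against 2.04 RPKM. Of the 119 families, 54 were past 2-fold higher and 0 lower, 31 were past 4-fold, and the median log2 change was 0.87.

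**Figure D2:**
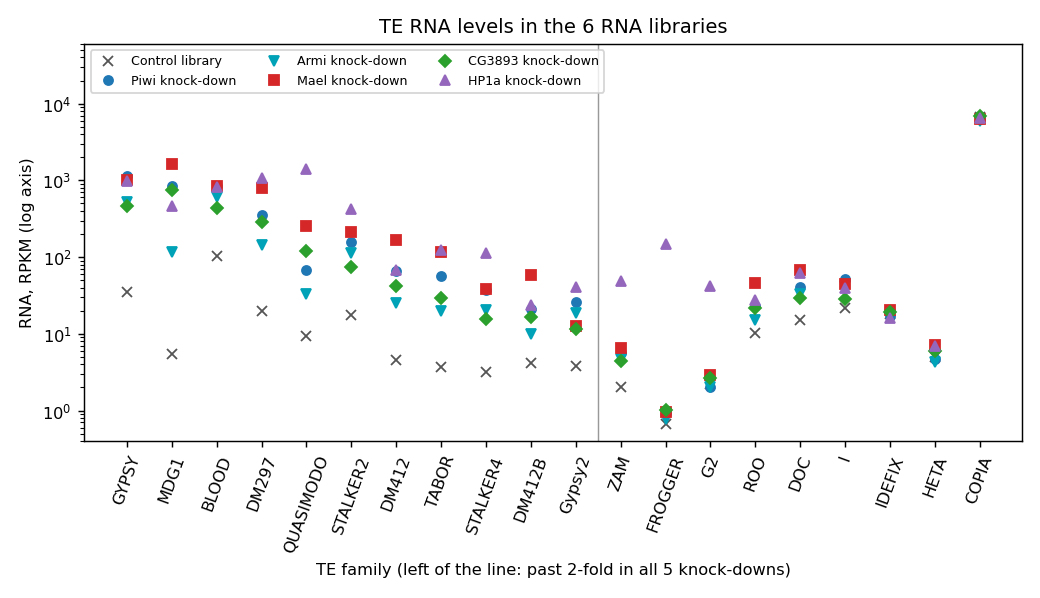
RNA levels of named TE families (RPKM, log axis) in the control library and the 5 knock-down libraries, 1 marker per library. The 11 families left of the line were past 2-fold in all 5 knock-downs, MDG1 from 5.45 RPKM in control to 1628 RPKM in Mael; FROGGER stands apart in HP1a at 150.5 RPKM, and COPIA has near equal levels.

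**Figure D3:**
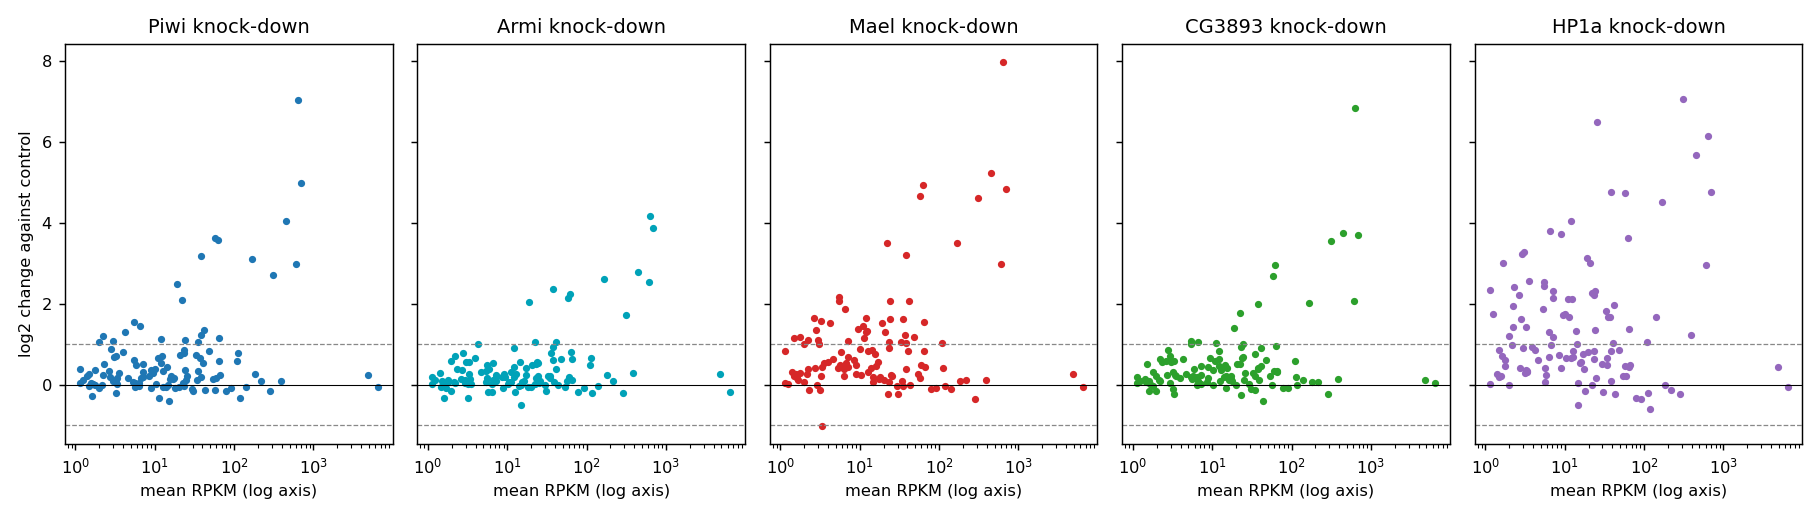
Log2 change of RNA against control, on the log2(RPKM + 1) scale, against the mean RPKM over the 6 RNA libraries (log axis), with 1 point for each of 119 TE families and 1 panel per knock-down. Dashed lines mark the 2-fold limits, past which 23, 13, 42, 16 and 54 families were higher in Piwi, Armi, Mael, CG3893 and HP1a.

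Across the knock-downs, 62 families were past 2-fold higher in at least 1 library and 11 in all 5: BLOOD, DM297, DM412, DM412B, GYPSY, Gypsy2, MDG1, QUASIMODO, STALKER2, STALKER4 and TABOR. The median log2 change of these 11 was 3.17 in Piwi, 2.37 in Armi, 4.62 in Mael, 2.70 in CG3893 and 4.74 in HP1a. Among Piwi, Armi, Mael and CG3893, the Mael library held the highest level of 9 of the 11, while Piwi was highest for GYPSY and Gypsy2. BLOOD, counted for Mael, was nearly equal in both, at 840.2 RPKM in Mael and 839.7 in Piwi. The targets were depleted unequally, with mael RNA at 10.3% of control, piwi at 30.1%, armi at 35.9% and CG3893 at 48.4%. The order of these libraries is therefore not an order of the factors' effects. In HP1a, 19 families were past 2-fold on the log2(RPKM + 1) scale that were under it in the other 4 libraries, and 10 of these were past 4-fold: ACCORD, DMHMR1, DMRT1A, DMRT1B, FROGGER, G2, G6, GYPSY2, GYPSY3 and ROOA. ACCORD, G6 and GYPSY3 were under 1 RPKM in every other library, and FROGGER was at most 1.03 RPKM there. They reached the mean of 1 RPKM only through HP1a. Such families can add to the numbers higher in HP1a but not to those lower. On the log2(RPKM + 1) scale 8 families were past 2-fold in at least 1 of the other knock-downs and under it in HP1a. Of these I, DOC6, POGON1 and COPIA2LT had plain ratios in HP1a of 1.83, 1.85, 1.60 and 1.67, while GTWIN, GYPSY10, GYPSY11 and ROVE, which are low in the control, had 2.47, 2.32, 2.94 and 2.08. Whether such differences between knock-downs exceed the spread between cultures was not tested.

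Between the piRNA factors, the log2 changes of the 119 families had Pearson's r of 0.971 for Piwi and Armi, 0.957 for Mael and CG3893, 0.948 for Piwi and CG3893, 0.941 for Piwi and Mael, 0.905 for Armi and CG3893, and 0.890 for Armi and Mael. HP1a gave r between 0.681, with Armi, and 0.723, with Mael. All comparisons share 1 control library, and simulated unchanged libraries against it gave r between 0.362 and 0.629 and a covariance of at most 0.0250, where the observed covariance ran from 0.665, for Armi and CG3893, to 1.45, for Mael and HP1a. Piwi and Mael shared 22 families past 2-fold, against 8.12 for independent lists of these sizes and 0.001 in the simulation. As the simulation holds no changed families, few pass 2-fold in it, and its shared number is near 0 in any case. The single control library cannot be split, so part of the excess may come from it, and families are not independent replicates.

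By class, 8 of 13 errantivirus-type families were past 2-fold in Piwi, 5 in Armi, 9 in Mael, 4 in CG3893 and 9 in HP1a, led by GYPSY, DM297, TABOR and QUASIMODO. The list's median log2 change was 1.08, 0.59, 1.17, 0.63 and 1.83 in that order, at percentiles 99.9, 99.5, 97.9, 99.5 and 95.9 of 10000 random lists matched on level. With a pseudocount of 5 the percentiles in Armi, Mael and CG3893 were 92.8, 94.2 and 91.1, inside the middle 95%, and that in HP1a was 98.4, outside it. Among 23 other Ty3/gypsy-type families 6 were past 2-fold in Piwi, 5 in Armi, 8 in Mael, 5 in CG3893 and 12 in HP1a, led by MDG1, with percentiles between 34.4 and 91.5. Of 28 non-LTR families, 4, 1, 10, 1 and 13 were past 2-fold in the same order, DOC among them except in CG3893, where its log2 change was 0.91, and the percentiles lay between 15.6 and 70.2. Of 7 Bel/Pao-type families 1, 0, 2, 1 and 5 were past 2-fold, with ROO the largest except in HP1a, where BATUMI, ROOA and MAX lay above it, at percentiles between 13.6 and 71.5. Among 4 Copia-type families only FROGGER and DM1731 in HP1a were past 2-fold, at percentiles between 8.57 and 37.2.

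Telomeric elements lay below the middle 95% of random lists in Piwi, Armi and HP1a, and DNA transposons in HP1a alone. None of the 4 telomeric entries, HETA, TAHRE, TART and TART_B1, was past 2-fold in any of the 5 knock-downs, and their median lay at percentile 1.65 in Piwi, 0.76 in Armi, 5.27 in Mael, 4.05 in CG3893 and 0.355 in HP1a. TART was at 98.9 RPKM in the control and 77.3 RPKM in HP1a, and HETA at 5.01 and 7.00 RPKM. Of 13 DNA transposon or helitron families 1, 0, 3, 1 and 3 were past 2-fold, TRANSIB2 the largest with log2 changes of 2.17 in Mael and 2.44 in HP1a. Their median log2 change in HP1a, 0.41, lay at percentile 0.925, and at 3.88 over families with a mean of at least 10 RPKM; in Piwi, Armi, Mael and CG3893 the percentiles were 17.4, 6.01, 18.5 and 46.5.

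The Pol II comparison asks whether the polymerase on TE sequences differs with the RNA. MDG1 held 588 RPM of Pol II reads in the control and was 5.23-fold higher in Piwi (5.00 to 5.46), 7.10-fold higher in Mael (6.80 to 7.42) and 6.35-fold higher in CG3893 (6.08 to 6.63). GYPSY was 3.07-fold, 2.74-fold and 2.55-fold higher in the same order, and STALKER2 2.66-fold, 2.97-fold and 2.70-fold. DM297 was 2.37-fold, 2.23-fold and 1.99-fold higher, and BLOOD 2.16-fold, 2.07-fold and 1.53-fold. DM412 was 1.69-fold higher in Piwi and 2.26-fold in Mael but 1.25-fold in CG3893, and QUASIMODO was 1.60-fold, 2.14-fold and 2.41-fold higher in Piwi, Mael and CG3893. COPIA was at 0.99-fold in Piwi, 0.82-fold in Mael and 1.42-fold in CG3893, and Gypsy1, which alone held 3.80% of the control reads, at 1.12-fold, 1.04-fold and 0.84-fold.

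The 142 families with a mean of at least 1 RPM include repeats in no TE list, such as 5S and DMSAT6. Past 1.5-fold, 11 were higher and 2 lower in Piwi, 12 higher and 5 lower in Mael, and 13 higher and 1 lower in CG3893. The median log2 changes were 0.04, 0.03 and 0.12, so the signal of most families lay close to control, without correction for background. Small entries were less certain: DM412B rested on 15 control reads and was 3.48-fold higher in Piwi (1.90 to 6.73), and SA, with 2 control reads, was 5.93-fold higher (1.26 to 55.7). Transib1, with 40 control reads, was 2.61-fold higher in Piwi (1.78 to 3.89). On the lower side, POGON1 at 0.38-fold (0.18 to 0.74) and PROTOP_A at 0.55-fold (0.42 to 0.72) in Mael had intervals below 1, while PEN2 and DMTOM1 in Piwi and G7 in Mael and CG3893 had intervals that reached 1. In CG3893, 7 families were past 1.5-fold once changes were centred on the median family, against 13 as deposited.

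Errantivirus-type families were also high in the Pol II ranking, at percentiles 99.0 in Piwi, 99.9 in Mael and 99.8 in CG3893, with 3, 4 and 4 of 13 past 1.5-fold. Other Ty3/gypsy-type families had 5, 4 and 3 of 29 past 1.5-fold and percentiles between 20.7 and 38.6. Of 33 non-LTR families 0 were past 1.5-fold higher in Piwi, Mael and CG3893, at percentiles between 4.65 and 32.7. Bel/Pao-type and Copia-type families had 0 past 1.5-fold higher, at percentiles from 3.75 to 46.4 and from 10.4 to 36.3. Telomeric entries had 0, at percentiles from 32.5 to 73.0, and DNA transposons had Transib1 in Piwi and CG3893, at percentiles from 54.4 to 87.5.

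**Figure D4:**
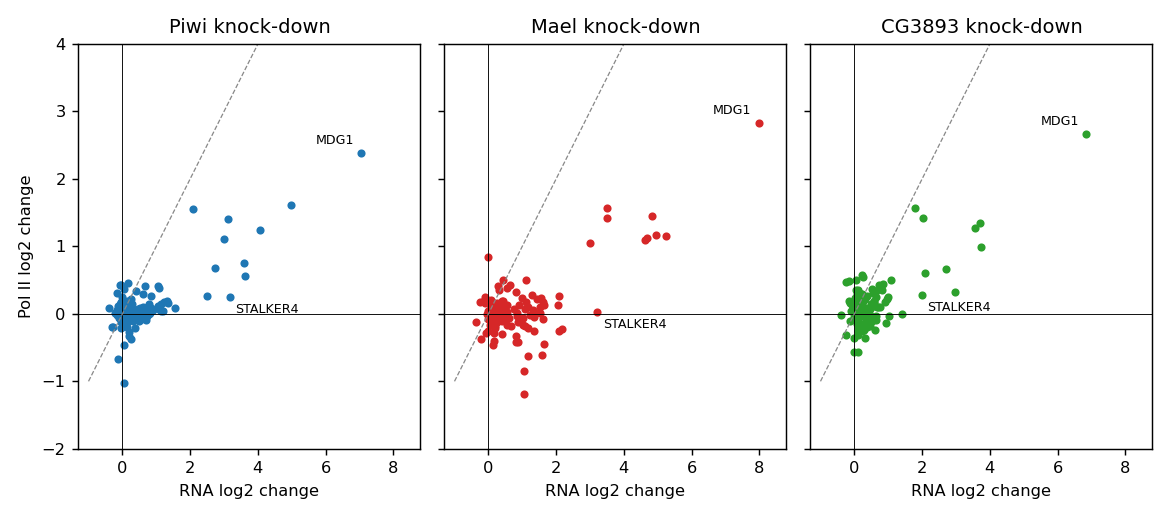
Log2 change of Pol II occupancy on the log2(RPM + 1) scale (vertical axis) against log2 change of RNA on the log2(RPKM + 1) scale (horizontal axis), with 1 point for each of 116 TE families and 1 panel per knock-down. The dashed line marks equal changes. MDG1 is farthest out, at an RNA change of 7.98 and a Pol II change of 2.83 in Mael. STALKER4 has high RNA with Pol II changes of 0.25 in Piwi, 0.03 in Mael and 0.28 in CG3893.

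Set side by side over 116 families, RNA and Pol II changes had Pearson's r of 0.801 and Spearman's rho of 0.441 in Piwi, 0.696 and 0.165 in Mael, and 0.763 and 0.305 in CG3893, across families that are not independent replicates. Without MDG1 and the family next farthest from the median RNA change, r was 0.671, 0.553 and 0.614. Of the families past 2-fold in RNA, 8 of 22 in Piwi, 9 of 40 in Mael and 8 of 14 in CG3893 were past 1.5-fold in Pol II as well, against 1.52, 3.45 and 0.966 for independent lists. Others went opposite ways in Mael: POGON1, PROTOP_A, GYPSY11 and GYPSY12A were past 2-fold higher in RNA but past 1.5-fold lower in Pol II. Their Pol II log2 changes were -1.18, -0.84, -0.62 and -0.61, and the interval of the GYPSY12A ratio reached 1 (0.349 to 1.07). No input library was used, so background reads from genomic copies cannot be told from polymerase and may draw Pol II ratios towards 1. G, for example, held 301 RPM of Pol II reads in the control, where 1 RNA read was counted. STALKER4 RNA was 11.9-fold higher in Mael while its Pol II signal was 1.02-fold (0.957 to 1.09). In Piwi and CG3893 the STALKER4 Pol II signal was 1.19-fold (1.12 to 1.26) and 1.22-fold (1.15 to 1.29). ROO RNA was 4.53-fold higher in Mael while its Pol II signal was 0.837-fold.

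Gene RNA was compared in the same libraries to see which genes accompany the TE families. Without short RNA genes, 25 genes were past 2-fold higher in all 5 knock-downs and 0 lower in all 5. All 5 comparisons divide by the same control library, so a low value there alone could place a gene among the 25. The gene ex, which encodes an upstream regulator of the Hippo growth pathway (2L, 431252 to 448701), stood at 2.43 RPKM in the control and at 28.5 in Piwi, 18.04 in Armi, 39.6 in Mael, 18.5 in CG3893 and 51.3 in HP1a. The gene CG32850 on chromosome 4 went from 31.5 RPKM to between 118 RPKM, in CG3893, and 527 RPKM, in HP1a. The ionotropic receptor gene Ir68a was at 0.53 RPKM in the control and between 6.72 and 29.5 RPKM in the knock-downs, and Ir7g at 0.90 and between 6.90 and 28.2. The chitin deacetylase gene Cda5, the receptor tyrosine kinase gene Ret, the potassium channel gene Shal and the Ski family gene Snoo were also in this group. CG15209, at 1.78 RPKM in the control and 14.2 to 40.2 RPKM in the knock-downs, lies inside the locus of sbr, whose own RNA was between 31.4 and 39.9 RPKM.

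**Figure D5:**
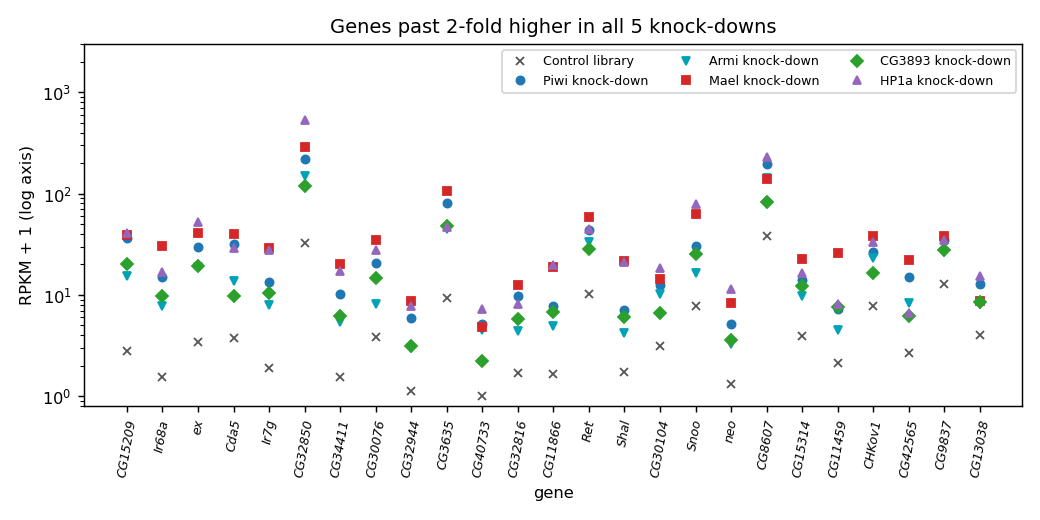
RNA of the 25 genes past 2-fold higher in all 5 knock-downs, as RPKM + 1 (log axis), in the control library and the 5 knock-down libraries, 1 marker per library and gene. The control marker is the lowest for every gene shown because the genes were chosen so, as for ex at 2.43 RPKM against 18.04 to 51.3 RPKM in the knock-downs.

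Of 7690 genes with a mean of at least 1 RPKM, 120 were past 2-fold higher and 36 lower in Piwi, 75 and 33 in Armi, 186 and 62 in Mael, 78 and 29 in CG3893, and 296 and 146 in HP1a. Short RNA genes such as those of snoRNAs took 11 of the 30 highest and 27 of the 30 lowest places; many were listed at 0 in a library, and their names are left out. Without them the numbers were 99 and 16, 57 and 6, 164 and 36, 57 and 4, and 273 and 122, a choice made after the values were seen. With a pseudocount of 5, 52, 34, 92, 35 and 142 genes were higher in the same order. With short RNA genes included, Piwi and Mael shared 105 of their 120 and 186 higher genes, against 2.90 for independent lists and 0.04 in the simulation. Without them, 92 of the 99 genes higher in Piwi were also higher in Mael. As the simulation holds no changed genes, few pass 2-fold in it, and its shared number is near 0 in any case. It cannot show how much of the sharing comes from the single control library. Pearson's r of gene changes was highest for Piwi and Mael, 0.733 against 0.522 simulated, and lowest for Armi and CG3893, where 0.530 lay below the simulated 0.634. It was barely above the simulation for Piwi and Armi, 0.661 against 0.612, for Piwi and CG3893, 0.664 against 0.617, and for Armi and Mael, 0.588 against 0.538. Covariances ran from 0.0493, for Armi and CG3893, to 0.169, for Mael and HP1a, against at most 0.0189 simulated. These r values and covariances include the short RNA genes. The simulated noise holds no outlying values such as theirs, so small differences between observed and simulated r cannot be interpreted.

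In Piwi the highest genes outside the short RNA class were CG15209, Ir68a, CG3635 at 79.4 against 8.33 RPKM, ex, Cda5 and CG14686 at 7.54 against 0.107 RPKM. Lowest, besides piwi itself, were CG34187 at 1.62 against 11.8 RPKM, the transcription cofactor gene nab at 9.04 against 21.3, dpr17, CG6579 and the arginine kinase gene Argk at 216 against 439 RPKM. In Armi ex, CG15209, Ir68a, CG3635, CG32850 and the tetraspanin gene TM4SF, at 158 against 36.9 RPKM, led. In Mael CG15828 was at 46.6 against 0.0890 RPKM, CG14686 at 42.7 against 0.107, CG42335 at 19.2 against 0.0591, and CG15278 at 21.8 RPKM where the control lists it at 0. Those 4 were also among the highest in CG3893, at 7.89, 12.4, 6.80 and 8.78 RPKM. Lower in Mael were the lactate dehydrogenase gene ImpL3, at 53.1 against 211 RPKM, CG15784, at 227 against 793, and CG6579.

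Some named genes share nearly all of their locus with another gene, so the split of reads between the pair is uncertain. CG12016 was at 20.1 RPKM in Mael, 16.1 in CG3893 and 15.7 in HP1a against 0.000529 in the control, while its partner CG42456 was lower by a like amount, and the pair's sum was 21.6 RPKM in the control, 22.5 in Mael, 21.4 in CG3893 and 19.9 in HP1a. The sum of CG42303 and CG42304 was 11.1 RPKM in the control, 10.4 in Mael and 12.0 in CG3893, although CG42303 was at 0.0101 RPKM in Mael against 11.0. CG6294, at 2.84 against 15.2 RPKM in Armi, and CG6299 had a sum of 18.1 RPKM there and 16.4 in the control. Prosalpha1, at 3.04 against 13.7 RPKM in Armi, shares its locus with CG30382, and their sum was 581 RPKM there and 605 in the control.

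In HP1a, heat shock genes were among the highest. Hsp70Ab was at 190.4 RPKM against 7.70 and Hsp70Aa at 181 against 7.44, near-identical copies whose reads may be split in any way. Small heat shock protein genes were higher as well: Hsp23 at 438 against 72.3 RPKM, Hsp26 at 445 against 112, and Hsp22 at 78.5 against 17.5. Of 24 heat and stress genes 13 were past 2-fold higher in HP1a and 1 lower, ImpL3, at 33.3 against 211 RPKM. The list's median log2 change was 1.21 in HP1a, against 0.18 in Piwi, 0.29 in Armi, 0.35 in Mael and 0.36 in CG3893, at percentile 100 of the random lists in each of the 5. CG12814 was at 30.7 against 0.466 RPKM. Lowest in HP1a were CG6579 at 1.90 against 25.4 RPKM, CG9521 at 1.67 against 21.2, CG42489 at 2.19 against 23.9, nab at 1.95 against 21.3, and CG32599 at 3.55 against 29.4; CG9521 lies inside the locus of Flo-2.

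Among genes past 2-fold without the short RNA class, 142 were higher and 94 lower in HP1a while under 2-fold in the other 4 knock-downs. In the other direction 4 genes, CG2233, CG42304, Kif3C and TM4SF, were past 2-fold higher in Piwi, Armi, Mael and CG3893 but not in HP1a; these were named after their values were seen, and CG42304 is part of a pair above. Kif3C, a kinesin gene on chromosome 4, stood at 35.6 RPKM in the control, between 76.6 and 94.5 RPKM in those 4 libraries and at 57.8 RPKM in HP1a.

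Pericentromeric genes in every knock-down but HP1a, and chromosome 4 genes in every knock-down but Armi, had medians above the middle 95% of random lists. All 5 comparisons divide by the same control library, so low values of these genes in it would lift them together, and this was not tested. Of 34 pericentromeric genes, Snap25, a synaptic vesicle fusion gene, was at 10.5 RPKM in Piwi and 10.3 in Mael against 3.63 in the control, and was the only one past 2-fold higher there. The list's median log2 change was 0.10 in Piwi, 0.09 in Armi, 0.20 in Mael and 0.14 in CG3893, each at percentile 100, and -0.04 in HP1a, at percentile 84.5. Parp, the poly(ADP-ribose) polymerase gene, was at 24.2 RPKM in HP1a against 102, and l(2)41Ab at 3.44 against 0.992. Of 54 chromosome 4 genes, CG32850 and Kif3C were past 2-fold higher in Piwi, Armi, Mael and CG3893, CG33521 also in Armi, and CG32850 and bt in HP1a; the percentiles were 100 in Piwi, Mael, CG3893 and HP1a and 87.5 in Armi, while the medians lay between -0.01 and 0.15.

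Of 23 genes of the piRNA pathway, the target was the only one past 2-fold lower in Piwi, Armi, Mael and HP1a, and squ, in HP1a, the only one past 2-fold higher. The RNA of squ was above the control's 14.2 RPKM in all 5, at 26.2 RPKM in Piwi, 20.8 in Armi, 29.3 in Mael, 21.6 in CG3893 and 36.9 in HP1a, with a log2 change of 0.99 in Mael, just under the limit. In HP1a zuc was at 12.2 against 19.7 RPKM, and the list's median log2 change was -0.26, at percentile 1.06, or 10.0 with a pseudocount of 5. In the other 4 knock-downs the percentiles lay between 27.1 and 97.2. Of 19 heterochromatin factor genes, which include the HP1a gene, wde was at 16.8 against 8.92 RPKM in HP1a, 0 were past 2-fold apart from the target, and the percentiles lay between 17.9 and 89.7.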

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

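The alternatives limited to families of the fixed lists, genes without short RNA genes and genes without coinciding loci were chosen only after the result was seen. Over 435 values computed under alternatives, 369 stayed within their limits and 66 moved. The limits were wide: a count stayed if it was within 1.5-fold of the reported count. Of the 369, 218 were list percentiles, and 14 of the 232 list percentiles moved. The 12 values of the RNA to Pol II correlation all stayed, which does not mean that they were unchanged. Reversals numbered 0, but counts and list percentiles have no sign to reverse, so this says nothing about them. Where a value moved, the cause was not tested unless said. No paired analysis was possible because each group holds 1 library. With a pseudocount of 5, which lowers every change of low features, genes past 2-fold higher numbered 52 in Piwi, 34 in Armi, 92 in Mael, 35 in CG3893 and 142 in HP1a, and lower 10, 16, 24, 15 and 80. TE families past 2-fold in RNA were then 14 in Piwi, 22 in Mael and 10 in CG3893, Pol II families in CG3893 8, and median RNA log2 changes of families 0.14 in Piwi, 0.35 in Mael, 0.16 in CG3893 and 0.63 in HP1a. With a pseudocount of 0.1, 134 genes were higher in Armi and 141 in CG3893, and 70 lower in Piwi. Over features with a mean of at least 10, which leaves fewer of them, genes higher numbered 48, 34, 69, 33 and 107 in the order given, genes lower 9, 12, 22, 12 and 84, and families higher in HP1a 31. With no filter, which adds families near 0, median RNA log2 changes were 0.0806 in Piwi, 0.0760 in Armi, 0.26 in Mael, 0.12 in CG3893 and 0.51 in HP1a, and median Pol II changes 0.000813 in Piwi and 0.0412 in CG3893. A limit of 4-fold left 11 families in Piwi, 14 in Mael, 8 in CG3893 and 31 in HP1a by construction, and a Pol II limit of 2-fold left 5 in CG3893. Pol II families past 1.5-fold in CG3893 were 7 centred on the median family, 8 scaled to the total over families and 8 among the fixed lists. Without short RNA genes, 16 genes were lower in Piwi, 6 in Armi, 36 in Mael and 4 in CG3893. Depth limits the Pol II values of families with few reads: SA in Piwi, for example, cannot be placed on either side of 1.5-fold.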

Other observations

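Of the tests in this part, those on short RNA genes, on the shared control for heat shock genes, on the depth of the HP1a library and on its scale were chosen only after the result was seen, as was the list of genes on heterochromatic or unplaced arms.

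Markers of the cells' own lineage stood higher in HP1a in part. Of 19 follicle markers, 6 were past 2-fold higher there, among them the yolk protein genes Yp1, at 6.50 against 1.62 RPKM, and Yp2, at 8.63 against 2.84, the transcription cofactor gene eya, at 47.9 against 16.6, and the adhesion gene Fas3, at 108 against 41.5. The list's median log2 change in HP1a was only 0.02, at percentile 92.4 of the random lists, while those in Armi and CG3893 were 0.12 and 0.15, at percentile 100 in both, or 86.0 and 62.1 over genes with a mean of at least 10 RPKM. The germline helicase gene vas was at 6.38 against 1.56 RPKM in HP1a, the only 1 of 19 germline markers past 2-fold in any of the 5 knock-downs, and the list's percentiles ran from 81.1 to 98.4. Of 5 hemocyte and fat body markers srp was past 2-fold in HP1a, at 21.6 against 8.83 RPKM, with percentiles from 6.04 to 76.4 over the knock-downs. Of 6 neuron and muscle markers, Act57B, an actin gene, was at 47.9 against 151 RPKM in HP1a and at 75.6 in Mael, and bt was at 5.29 against 1.17 in HP1a; percentiles ran from 29.5 to 89.5.

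The pro-apoptotic gene W (hid) was at 0.447 RPKM in the control, 2.12 in Piwi, 1.34 in Armi, 2.21 in Mael, 1.08 in CG3893 and 9.88 in HP1a, and Corp at 5.43 in HP1a against 1.98. The 21 apoptosis and DNA damage genes as a list had medians slightly below control, from -0.08 in Mael to -0.17 in HP1a, at percentiles from 0.46 to 33.4. Of 4 immune genes, PGRP-LB was at 1.13 RPKM in Piwi against 3.60 and vir-1 at 9.18 in HP1a against 4.05, with percentiles from 9.97 to 71.7. Of 11 siRNA and miRNA genes 0 were past 2-fold, with Dcr-2 at 110 RPKM in HP1a against 159 and percentiles from 22.2 to 83.4. Of 28 S and M phase genes 0 were past 2-fold, with stg at 26.0 RPKM in HP1a against 39.3 and RnrS at 168 against 226, and percentiles from 6.76 to 75.7. Of 49 genes on heterochromatic or unplaced arms, CG40733, listed at 0 in the control, was the only 1 past 2-fold in Piwi, and 7 were higher and 2 lower in HP1a, Parp among the latter; percentiles were 99.8 to 100 in Piwi, Armi, Mael and CG3893 and 29.9 in HP1a.

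Genes past 2-fold higher in Piwi numbered 120, or 99 without short RNA genes, and 92 of these 99 were past 2-fold in Mael too. Low chance values in the shared control are argued against as the whole cause by the ratio of the Mael to the Armi library. This ratio uses neither the control nor the Piwi library. Its median log2 over the 99 genes was 0.89, where random lists gave -0.04 to 0.05. Low control values may still add a part: 99 of the 99 genes were above control in Armi, 97 in Mael, 97 in CG3893 and 98 in HP1a. Unstable short RNA genes made up 17.5% of the 120, too few to account for the group. Of the 99 genes, 26.3% had another of them within 50 kb, above the middle 95% of random gene sets (4.04% to 22.2%). These were 26 genes in 10 groups, the largest a block of 6 genes on 3R that holds CG34432 and CG34433. The share without this block was not tested, so the excess may rest on it. A candidate explanation is an effect that reaches neighbouring genes, for instance from a TE insertion, whose positions were not analysed here. Pairs of related neighbours such as Ir7f and Ir7g would give the same clustering, and this stays open.

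Heat shock genes were highest in HP1a, with a list median of 1.21, though not higher there alone: Hsp70Aa was at 12.4 RPKM in Piwi, 18.5 in Armi, 20.3 in Mael and 16.2 in CG3893, against 7.44 in the control and 181 in HP1a. Reads shared between the Hsp70 copies are argued against as the whole cause, since the 19 genes other than these copies had a median log2 change of 0.54, above random lists (-0.27 to 0.02), and 8 of them were past 2-fold. A low value in the shared control, which would add to every comparison, is argued against as the whole cause by the ratio of the HP1a to the Armi library, whose median log2 over the 24 genes was 0.90, where random lists gave -0.19 to 0.03. It may still add a part. The same comparison argues against the lower depth of the HP1a library, since depth acts on every gene of like level and the random lists come from the same libraries. Earlier forms of the depth test used the list's own percentile against control, and then asked for a library of like depth, and both were replaced after their values were seen. A response to the loss of HP1a and a stress of that culture cannot be separated with 1 library, and may both be at work.

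The 10 families past 4-fold in HP1a and under 2-fold in the other 4 knock-downs, on the log2(RPKM + 1) scale, were led by FROGGER and G2, which was at 41.8 RPKM against 2.23. In 0 of the 10 families did the lower bound of the ratio lie under 2-fold, and the lowest bound was 4.70, for DMRT1A. The families were picked by high values in the same library, so this could hardly come out otherwise and decides nothing about few reads. The fewest HP1a reads among them were 148, for DMHMR1, against 24 in the control. ACCORD, FROGGER, G6 and GYPSY3 also reached the mean of 1 RPKM only through the HP1a library. A common scale shift of 4-fold in the HP1a library is argued against, as 40.4% of the 109 other families were past 2-fold, a share that follows from counts already seen, where such a shift would lift nearly all of them. A smaller common rise that adds to these changes is not excluded by this. An earlier form of that test, on the median log2 change of the other families, gave 0.84 and decided nothing, and it was replaced after its value was seen. Several of the 10 were also above control in other knock-downs: DMRT1A was 1.80-fold in Piwi, 1.52-fold in Armi, 1.95-fold in Mael and 1.62-fold in CG3893, ROOA 1.77-fold and GYPSY2 1.81-fold in Mael, and DMHMR1 2.11-fold in CG3893 (1.26 to 3.60). Whether these families depend on HP1a apart from the piRNA factors was not tested, and a difference of that 1 culture stays open.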
